A study of Mus musculus with 46 samples.

How the data were processed

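The series holds 46 mouse RNA-seq samples. Processed values were analysed for the 14 libraries of cultured thyroid tumour cells: 4 RP lines (Rb and p53 mutant), 4 RPM lines (Rb, p53 and Max mutant), 3 libraries of an RPM line with an empty vector and 3 of that line with Max added back. The 32 tumour libraries (11 RP thyroid, 3 RPM thyroid, 9 RP pituitary, 8 RPM pituitary and 1 without a group in the labels) were not analysed here. Groups and replicate numbers came from the sample titles and genotypes. The animal identifier in the library name of RPM replicate 1 also appears on tumour libraries labelled Rb/p53 mutant. The group given by the cell library's own label was kept, and the limma counts of called genes, of genes opposite in both comparisons and of genes that differed between the comparisons are also given without that library. Per the labels' protocols, cells were grown in DMEM with 10% serum, total RNA was extracted with Trizol and a column kit, and libraries were made with an Ultra RNA kit. Whether the reads were counted by strand is not given in the sources used here, so reads of overlapping antisense genes cannot be told apart.

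Per the submitters' processing notes, reads were made with bcl2fastq 1.8.4, aligned with TopHat2 2.1.0, counted with HTSeq 0.6.1 and analysed with edgeR (no version given), and the genome build was mm10. The roles of these tools are inferred from what each is for. The annotation release and the filter that chose the listed genes are not given in the sources used here. There were 2 tables, of 14360 genes for the lines and 14056 for the addback experiment, 13528 of them shared, and the authors normalised the 2 separately. Per the file headers, the authors deposited a TMM-normalised CPM signal per gene and library, which is the read count divided by library size times a TMM factor. The deposited RPKM values, per the file headers, are the same levels scaled to gene length; they were not tested. Per the file headers, the authors also deposited log2 fold changes and average log2 levels, p-values and FDR values from edgeR, and a score of -1, 0 or 1 for their call of each gene.

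Each library's CPM values were whole multiples of the value of 1 read. Dividing by that step gave whole reads, within 0.01 of a read, for 100% of values in every library, with totals of 6738614 to 8498396 reads and TMM factors of 0.972 to 1.0477. The value of 3 reads, used as the floor for a gene with no read in a library, was 0.353 to 0.458 CPM; floors and the smallest counts bound counting error only. The 10 genes with most reads took 2.49 to 4.83% of the reads. Replicates were compared by a chi-square per degree of freedom over genes. It was 21.8 to 82.1 between lines of a group, 1.81 to 1.97 between empty vector libraries, 1.88 between addback replicates 1 and 2, and 16.3 and 13.8 between these and addback replicate 3. All values lay above sampling noise, and no library was merged. Gene identifiers were matched to GENCODE vM21 on GRCm38, the assembly that mm10 names, for coordinates: 14354 and 14050 identifiers were found, 14033 and 13732 with the same version. The tables list protein-coding genes (13152 and 12903) and long noncoding RNAs (1208 and 1153). Symbols turned into dates (23 and 22 genes) were left out of the named genes, and 4 and 2 symbols are shared by more than 1 identifier.

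The groups, designs, gene lists, the processing choices to be varied and the rule for named genes were fixed before the data were examined. The design named edgeR's quasi-likelihood test for raw counts and, where normalised values were found, limma-trend on log2(CPM + 1). Since the tables hold normalised values, limma-trend was the test used, with a pseudocount of 1 and Benjamini-Hochberg adjusted p under 0.05, two-sided, on all listed genes. Fold changes are therefore on the log2(CPM + 1) scale, which understates changes of low genes. Each comparison was fitted on its own libraries only (8 and 6) without covariates. The count tests on recovered reads were run as alternatives. Max, Rb1 and Trp53 and the per-library means of gene lists were also tested by exact permutation. The directions in both comparisons were related by Fisher's exact test and by correlation across genes. The difference between the comparisons was (RPM over RP) minus (empty vector over addback). It was tested gene by gene with limma voomWithQualityWeights on the recovered reads of all 14 libraries. The design named this test for raw counts only. The deposited calls are given as the authors': the authors' deposited table calls 247 genes higher and 355 lower in RPM lines and 2656 higher and 1845 lower with addback. Of the limma calls, 33 of 48 and 4390 of 7478 are also called in the authors' deposited table, with the same sign. The smallest absolute log2 change of a deposited call was 0.88 in the lines and 0.59 with addback. The limma calls had no such minimum, but a minimum cannot make the deposited set of the lines the larger. On the log10 scale the deposited p-values correlated with those of edgeR's exact test with trended dispersion on recovered reads. The correlation was 0.9998 in the lines and 0.9999 with addback. The 2 sets of calls thus rest on unlike tests, besides any minimum. How often that exact test called unchanged genes in simulated lines is given below.

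Genes were tested in 27 lists of pathways and cell type markers. Lists with at least 3 listed members were tested, apart from the sex-linked genes, which left 24 per comparison, by camera with a preset inter-gene correlation of 0.01, by camera with an estimated correlation and by fry, with adjustment over the lists. The lists are the MYC/MAX/MLX network, classical MYC targets, ribosome biogenesis, ribosomal proteins, translation initiation, nucleotide synthesis, serine and one-carbon metabolism, the ATF4 amino acid and stress response, glycolysis, MLX partner targets with lipogenesis, cholesterol synthesis, oxidative phosphorylation, lysosome, DNA replication and mitosis, p53 targets, germline genes, interferon response, MHC class I presentation, and markers of neuroendocrine and C cells, thyroid follicular cells, fibroblasts, epithelium, leukocytes, endothelium, Schwann cells and parathyroid, with sex-linked genes. Members of a list are counted with adjustment over all genes and with adjustment over the list alone. Some genes stand in more than 1 list.

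Named genes were chosen by a rule: the engineered genes, the network members, in each comparison the 10 largest changes up and the 10 down among called genes with an average log2 level of at least 3 in the authors' deposited table and no overlap between groups (without predicted genes, pseudogenes and clone names), the 3 list members with the smallest adjusted p where a member passed or 1 where none did, and the 10 genes with opposite calls in both comparisons whose smaller change was largest. The rule gave 141 genes, of which 83 were taken for the text; 1 gene that the rule names is not reported here. Alternatives were other tests (edgeR quasi-likelihood, edgeR exact with trended dispersion, DESeq2, limma voom), DESeq2 size factors, no scaling beyond library size, a stricter filter (at least 10 reads in every library of a group and a mean of at least 1 CPM), pseudocounts of 0.25 and 5, 1 fit over all 14 libraries, the replicate number as a block, chromosome medians subtracted, adjusted p under 0.01, at least 2-fold change, and each library left out in turn. Of these, 65 were planned and 37 were added after seeing the data.

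The tests were tested on simulated reads for the real genes with 200 genes changed. In simulated lines limma-trend on 14360 genes recovered 0% of 2-fold and 75.5% of 4-fold changes, with 8 unchanged genes among 159 calls in the 4-fold simulation, and edgeR's quasi-likelihood test recovered 73.5% of the 4-fold changes. edgeR's exact test with trended dispersion recovered 25.5% of 2-fold and 85.5% of 4-fold changes, with 75% and 48.5% of its calls unchanged genes. In the simulated addback experiment, on 14056 genes, limma-trend recovered 98% of 2-fold and 100% of 4-fold changes. Unchanged genes made up 14 of its 210 calls (6.7%) in the 2-fold and 19 of 219 (8.7%) in the 4-fold simulation. The test of the difference recovered 84.2% of 393 genes changed 4-fold among 13528, with 18 unchanged genes called. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.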

Results

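RNA sequencing was used to measure transcripts in cell lines grown from thyroid tumours of mice. The mice carried conditional mutations of Rb and p53, or of Rb, p53 and Max, recombined in neuroendocrine cells by a tamoxifen-inducible Cre under Ascl control. The lines are called RP and RPM here. MAX is the partner with which MYC proteins and the MXD, MNT and MGA repressors bind DNA, and the question was how its loss alters transcription through the extended MYC network. Values of 14 libraries were analysed: 4 RP lines, 4 RPM lines, and a separate experiment with 3 libraries of an RPM line transduced with an empty vector and 3 of the same line transduced to express Max again (Max addback). By the library names that line is RPM replicate 2. The 32 tumour libraries of the series were not analysed here. Reads over the listed genes totalled 8242657 to 8498396 in the RP libraries, 7829982 to 8408913 in the RPM libraries, 6738614 to 7238672 with empty vector and 7426964 to 7912573 with addback. Levels are given as CPM, the authors' read counts scaled to library size. At this depth 3 reads correspond to 0.353 to 0.458 CPM. Such floors cover counting error only. The p-values measure the spread between these samples: each of the 8 lines has its own name, whereas all 6 libraries of the addback experiment belong to 1 line, and whether they were separate cultures is not given in the sources used here.

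The engineered genes were examined first. Max (ENSMUSG00000059436.13; mm10, chromosome 12, 76937269 to 76962201, minus strand) was read in every library, at 65.2, 44.7, 50.8 and 57.5 CPM in RP replicates 1 to 4 and at 80.9, 103, 68.9 and 100 CPM in RPM replicates 1 to 4. Its mean was 54.6 ± 8.8 CPM (SD, n = 4) in RP and 88.2 ± 16.2 CPM (SD, n = 4) in RPM lines. An exact two-sided permutation test gave p = 0.0286, the smallest value 4 against 4 libraries allow. Over all genes limma gave an adjusted p = 0.161. Counts over a whole gene do not show whether an exon was removed, so these levels check nothing about the genotype labels. With addback, Max rose from 88.5 ± 6.73 CPM (SD, n = 3) to 240 ± 17.2 CPM (SD, n = 3), a log2 change of 1.43 (SE 0.09, limma adjusted p = 5.75e-07). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Rb1 (chromosome 14, 73183673 to 73325822) averaged 240 CPM in RP and 169 CPM in RPM lines (exact two-sided permutation p = 0.0857), with single libraries from 140 to 296 CPM, and 212 and 211 CPM with empty vector and addback (exact permutation p = 1). Trp53 (chromosome 11, 69580359 to 69591873) averaged 11.5 CPM in RP and 13.7 CPM in RPM lines (exact two-sided permutation p = 0.343), and 12.6 and 10.8 CPM in the addback experiment (exact permutation p = 0.1).

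The first comparison set the 4 RPM lines against the 4 RP lines. Named genes higher in RPM lines included Rrp12, Nol8, Rcl1, Ltv1 and Pus7. Rrp12, a factor of ribosomal subunit maturation and export, stood at 52.1 ± 5.12 CPM in RP and 136 ± 10.9 CPM in RPM lines (SD, n = 4 each), a log2 change of 1.37 (SE 0.12, limma adjusted p = 0.0179). Nol8, a nucleolar protein, rose from 40.4 ± 9.73 to 119 ± 10.5 CPM, a log2 change of 1.56 (SE 0.18, adjusted p = 0.0325). Rcl1, a factor of small subunit processing, rose from 21.6 ± 4.59 to 55.6 ± 3.87 CPM, and Ltv1, which acts in small subunit assembly, from 38.3 ± 6.28 to 84.7 ± 5.31 CPM (adjusted p = 0.0338 each). The pseudouridine synthase gene Pus7 rose from 27.8 ± 6.87 to 77.6 ± 14.6 CPM, a log2 change of 1.46 (adjusted p = 0.0381).

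Large rises in RPM lines were found for Tdrd1, Rbm46, Ccdc36 and Taf4b, which had little RNA in RP lines. Tdrd1, a Tudor protein of the piRNA pathway (chromosome 19, 56826209 to 56870012), stood at 1.21 ± 2.34 CPM in RP and 51.8 ± 18.2 CPM in RPM lines, a log2 change of 4.99 (SE 0.58, adjusted p = 0.0325). The RP mean rests on RP replicate 4, with 4.71 CPM; the other RP libraries had 0, 0 and 0.122 CPM. Rbm46, an RNA-binding protein of germ cells, rose from 1.18 ± 1.85 to 26.6 ± 14.6 CPM, and Ccdc36, a meiotic recombination factor, from 2.65 ± 2.55 to 28.8 ± 9.42 CPM (adjusted p = 0.0381 and 0.049). Taf4b, a TFIID subunit of germ cells, rose from 2.6 ± 1.17 to 16.9 ± 4.06 CPM, a log2 change of 2.35 (SE 0.31, adjusted p = 0.0338). Stag3, a meiotic cohesin subunit, averaged 12.7 ± 22.6 CPM in RP and 313 ± 34.4 CPM in RPM lines and missed the threshold (adjusted p = 0.0562), with 46.6 CPM in RP replicate 4 and at most 3.01 CPM in the other RP lines. RP replicate 4 also held 344 CPM of Xist, a transcript of the inactive X chromosome chosen after its values were seen, together with Y-linked Ddx3y at 53.3 CPM. The zinc finger gene Zscan18 rose from 5.83 ± 2.42 to 23.3 ± 1.07 CPM (adjusted p = 0.0381). Scfd2 rose from 15.7 ± 3.04 to 45.2 ± 7.55 CPM (adjusted p = 0.0375).

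Named genes lower in RPM lines included Cdkn1c, Rtn1, Fam102b and Tlx3. Cdkn1c, which encodes the inhibitor p57, fell from 78.4 ± 18.7 to 10.4 ± 6.14 CPM (SD, n = 4 each), a log2 change of -2.96 (SE 0.41, limma adjusted p = 0.0365). Rtn1, a reticulon of neuroendocrine cells, fell from 151 ± 46.3 to 25.4 ± 6.57 CPM, a log2 change of -2.52 (SE 0.26, adjusted p = 0.0179). Fam102b fell from 86.3 ± 23.1 to 17.7 ± 2.98 CPM, a log2 change of -2.2 (SE 0.22, adjusted p = 0.0179). The homeobox gene Tlx3 stood at 15.3 ± 6.42 CPM in RP and at 0.253 ± 0.276 CPM, near the counting floor, in RPM lines (adjusted p = 0.0179). Arnt2, Plxnd1, Nrxn3 and Fzd3, which encode a bHLH-PAS factor, a semaphorin receptor, a neurexin and a Wnt receptor, fell with log2 changes of -3.13, -2.79, -2.72 and -1.2 (adjusted p = 0.049, 0.0375, 0.0338 and 0.0394). The protocadherins Pcdhb5 and Pcdhb9 fell from 25.6 to 8.61 CPM and from 13.8 to 3.44 CPM; reads of this family can be shared between near-identical copies, so both values are uncertain.

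Among the 13 members of the MYC/MAX/MLX network, Mnt rose in RPM lines from 55.8 ± 3.17 to 112 ± 12.8 CPM (SD, n = 4 each), a log2 change of 0.99 (SE 0.12, limma adjusted p = 0.0325). MNT is a MAX partner that represses transcription. The other 12 members missed the threshold over all genes. Adjusted over the list alone, 5 were higher, namely Max, Mnt, Mxi1, Mxd4 and Mga, and 2 were lower, Myc and Mycl. Myc averaged 4.35 ± 1.24 CPM in RP and 0.75 ± 0.999 CPM in RPM lines, and Mycl, the paralog read most in RP lines, 249 ± 110 and 83.1 ± 158 CPM (adjusted p = 0.125 and 0.219 over all genes). RPM replicate 1 held 320 CPM of Mycl against 2.84 to 6.61 CPM in the other RPM lines. Mycn was at 9.97 and 11.1 CPM (adjusted p = 0.933). The repressor genes Mxi1, Mxd4 and Mxd3 averaged 94.7, 87.5 and 32.5 CPM in RP and 163, 145 and 57.1 CPM in RPM lines, Mxd1 32 and 26.4 CPM, and Mga 244 and 314 CPM. Mlx and its partners Mlxip and Mlxipl averaged 49.5, 64.9 and 62 CPM in RP and 61, 73.3 and 43.9 CPM in RPM lines. The list's median log2 change was 0.29 and its mean -0.15, a difference in sign, with camera upward at an adjusted p = 0.0533 (adjusted p = 0.36 with an estimated correlation, range 0.0107 to 0.36). It passed without RP replicate 3 (0.0278), RPM replicate 3 (0.0463) or RPM replicate 4 (0.0455).

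**Figure D1:**
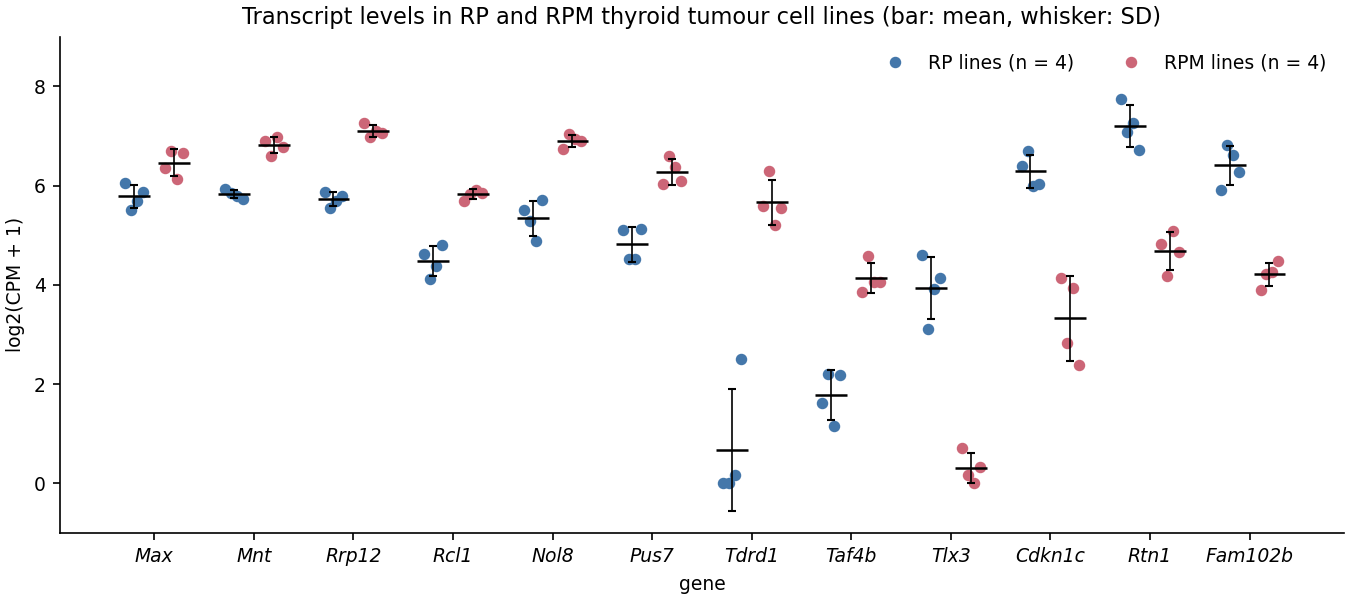
Levels of 12 genes in the 4 RP and 4 RPM lines, as log2(CPM + 1) on the vertical axis; each dot is 1 library, the bar is the group mean and the whisker the SD. Except for Max, whose change missed the threshold (adjusted p = 0.161), the genes drawn passed it, and for all 12 the RP and RPM dots do not overlap.

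Of the 24 gene lists tested, ribosome biogenesis had the smallest p by camera, which sets a list against the other genes. Over all genes 2 of its 41 members passed, Rrp12 and Rcl1, and 21 did when adjusted over the list alone, all higher. The median log2 change was 0.47, with 97.6% of members above 0. camera gave an adjusted p = 3.74e-17 with its preset correlation and an adjusted p = 0.36 with an estimated correlation. Over all alternatives the range was 4.37e-18 to 0.36. Per library, the mean log2(CPM + 1) of these genes was 5.71 ± 0.16 in RP and 6.21 ± 0.06 in RPM lines (SD, n = 4). The exact two-sided permutation p was 0.0286, the smallest possible, and 0.229 adjusted over the lists. Utp20, a component of small subunit processing, averaged 71 ± 17.6 and 154 ± 7.29 CPM and missed the threshold (limma adjusted p = 0.051). None of the 20 classical MYC targets passed over all genes (2284 of all 14360 genes had an unadjusted limma p under 0.05), and 5 were higher when adjusted over the list alone. Their median was 0.37 and camera's adjusted p = 0.000144 (adjusted p = 0.36 with an estimated correlation, range 9.71e-06 to 0.36). Srm, which encodes spermidine synthase, averaged 72.9 ± 10.4 and 116 ± 4.57 CPM (limma adjusted p = 0.0832).

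The 48 ribosomal proteins had no member past the threshold by limma, over all genes or adjusted over the list alone. Their median log2 change was 0.18, and copies of these genes elsewhere in the genome make single values uncertain. As a list they passed camera upward with an adjusted p = 0.00213 (adjusted p = 0.507 with an estimated correlation, range 6.47e-05 to 0.507). Of 13 listed germline genes Tdrd1 passed over all genes and 3 were higher when adjusted over the list alone, among them Stag3. Their median was 0.7 and camera's adjusted p = 0.00292 (adjusted p = 0.469 with an estimated correlation, range 0.000106 to 0.469). RP replicate 4, the library with both Xist and Ddx3y, held the most Tdrd1 and Stag3 of the RP lines. All 10 genes of MHC class I presentation, which displays peptides to T cells, lay above 0 with a median of 0.76. Adjusted over the list alone 2 passed, and camera gave an adjusted p = 0.00292 (adjusted p = 0.507 with an estimated correlation, range 0.000452 to 0.507). Per library, the mean log2(CPM + 1) of these genes was 5.78 and 5.77 in RPM replicates 3 and 4, 4.84 in RPM replicate 2 and 4.45 in RPM replicate 1, against 3.98 to 4.67 in the RP lines. All 11 epithelial genes lay below 0 with a median of -1.47 and none passed limma's threshold, also when adjusted over the list alone. camera gave an adjusted p = 0.00496 (adjusted p = 0.507 with an estimated correlation, range 3.4e-06 to 0.507), lost without RPM replicate 2 (0.0609). RPM replicate 1 went the other way, with a mean log2(CPM + 1) of these genes of 8.2, above the highest RP line (7.41), whereas the other RPM lines lay at 4.01 to 5.51. Without it camera gave the lowest value of the range, 3.4e-06. Esrp1, an epithelial splicing regulator, averaged 266 ± 55.6 CPM in RP and 114 ± 107 CPM in RPM lines (adjusted p = 0.308). The 3 listed endothelial genes had a median of -0.95, with 2 lower when adjusted over the list alone, and camera gave an adjusted p = 0.0214 (adjusted p = 0.36 with an estimated correlation, range 0.0097 to 0.36; 0.0513 without RPM replicate 3).

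Several lists of metabolism and growth were upward by camera with small medians and no member past the threshold over all genes. Nucleotide synthesis, 23 genes, had a median log2 change of 0.19 and an adjusted p = 0.00292 (adjusted p = 0.507 with an estimated correlation, range 5.89e-05 to 0.507). Its member Nme2 averaged 6.93 and 16.1 CPM and was the 1 gene higher when adjusted over the list alone. Serine and one-carbon metabolism, 22 genes, had a median of 0.28 and an adjusted p = 0.0107 (adjusted p = 0.507 with an estimated correlation, range 0.00142 to 0.507). Shmt1, a serine hydroxymethyltransferase, averaged 60.5 and 123 CPM and was the 1 gene higher when adjusted over the list alone. Without RPM replicate 1 the value of either list was 0.0612. No member passed, also when adjusted over the list alone, among 27 lysosomal genes, with a median of 0.29 and an adjusted p = 0.00292 (adjusted p = 0.507 with an estimated correlation, range 0.000242 to 0.507; 0.0516 without RPM replicate 3). The same held for 35 genes of DNA replication and mitosis, with a median of 0.2 and an adjusted p = 0.00396 (adjusted p = 0.512 with an estimated correlation, range 0.000143 to 0.512; 0.146 without RP replicate 2 and 0.0579 without RPM replicate 2). It held too for 35 genes of oxidative phosphorylation, with a median of 0.12 and an adjusted p = 0.0459 (adjusted p = 0.631 with an estimated correlation, range 0.000511 to 0.631). That last call was lost without RP replicate 1 (0.304), RP replicate 4 (0.0572), RPM replicate 1 (0.0792), RPM replicate 2 (0.255) or RPM replicate 4 (0.182). In all, 12 of 24 lists passed by camera with its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.36. In exact two-sided permutation tests of the means per library, MYC targets and germline genes reached p = 0.0286, the smallest possible, and ribosomal proteins and endothelial genes p = 0.0571. The others called by camera, besides ribosome biogenesis, were at p = 0.0857 (serine and one-carbon metabolism, lysosome), 0.114 (nucleotide synthesis), 0.143 (MHC class I, epithelial genes), 0.2 (replication and mitosis) and 0.257 (oxidative phosphorylation) in the same exact test. None was under 0.229 after adjustment over the lists. fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 4: the network, MYC targets, ribosome biogenesis and endothelial genes.

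Over all 14360 genes, limma called 30 higher and 18 lower in RPM lines; 24 and 16 of these changed at least 2-fold. RP and RPM libraries did not overlap at any of the 48, as at 9.37% of all genes, against 2.86% given by chance. An unadjusted p under 0.05 was found for 2284 genes, where 718 would come by chance. The count depended on the tool and the library. On the recovered reads edgeR's quasi-likelihood test called 1 higher and 2 lower (Rrp12, Rtn1 and Fam102b, adjusted p = 0.0256, 0.0491 and 0.0488) and DESeq2 350 and 308. Leaving out 1 library gave 1 higher and 6 lower (RP replicate 1), 6 and 6 (RP replicate 2), 0 and 0 (RP replicate 3), 13 and 4 (RP replicate 4), 77 and 184 (RPM replicate 1), 7 and 4 (RPM replicate 2), and 0 and 0 (RPM replicate 3 and likewise RPM replicate 4). Where limma called none, 1469, 1805 and 1692 genes had an unadjusted p under 0.05. The animal identifier in the name of RPM replicate 1 also stands on tumour libraries labelled Rb/p53 mutant.

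The second comparison set addback against empty vector libraries of the line of RPM replicate 2. The addback libraries also nearly lack Y-linked transcripts that the empty vector libraries and the untransduced line hold. An effect of Max and other differences between the transduced cells therefore cannot be told apart. With addback 35 of 41 ribosome biogenesis genes and 13 of 21 classical MYC targets fell by limma. Rrp12 fell from 134 ± 9 to 56.8 ± 6.26 CPM (SD, n = 3 each), a log2 change of -1.23 (SE 0.1, limma adjusted p = 4.32e-06), and Srm from 167 ± 9.31 to 59.2 ± 6.26 CPM, a log2 change of -1.49 (SE 0.09, adjusted p = 6.86e-07). Of 23 neuroendocrine and C cell genes 18 rose, among them the prohormone convertase gene Pcsk1, at 0.536 ± 0.0952 CPM with empty vector and 270 ± 47.3 CPM with addback (log2 change 7.45, SE 0.14, adjusted p = 6.57e-10). Of 11 epithelial genes 9 rose, with E-cadherin (Cdh1) going from 14.6 ± 2.12 to 183 ± 13.1 CPM, while the mesenchymal filament gene Vim fell from 162 ± 32.6 to 2.41 ± 0.182 CPM (log2 change -5.56, SE 0.14, adjusted p = 3.18e-09).

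Of the 41 ribosome biogenesis genes, 35 fell with addback and 0 rose, with the same counts when adjusted over the list alone. The median was -0.64 and camera's adjusted p = 5.51e-10 (adjusted p = 0.229 with an estimated correlation, range 2.98e-11 to 0.229). Rcl1 fell from 73.1 to 29.8 CPM and Nop58, a core box C/D ribonucleoprotein, from 239 to 141 CPM. Of 48 ribosomal proteins 37 fell and 1 rose, as when adjusted over the list alone, with a median of -0.62 and an adjusted p = 7.72e-08 (adjusted p = 0.601 with an estimated correlation, range 2.23e-12 to 0.601). The list's mean log2(CPM + 1) was 6.29 to 6.32 in the empty vector libraries, 5.58 and 5.65 in addback replicates 1 and 2 and 6 in addback replicate 3, a library that stood apart from the others; without it camera gave the lowest value of the range, 2.23e-12. Rps19 went from 114 to 54.9 CPM and Rpl22 from 481 to 222 CPM. Among 21 classical MYC targets 13 fell and 1 rose, as when adjusted over the list alone, with a median of -0.4 and an adjusted p = 0.00338 (adjusted p = 0.47 with an estimated correlation, range 0.000357 to 0.47). Odc1, the first enzyme of polyamine synthesis, fell from 237 to 108 CPM. The gene that rose was Tert, the telomerase reverse transcriptase, from 0.729 to 8.06 CPM (adjusted p = 5.76e-07 and 8.27e-06). Of 21 translation initiation genes 11 fell and 0 rose (12 and 0 when adjusted over the list alone), including Eif3a from 677 to 405 CPM. Their median was -0.26 and the adjusted p = 0.0189 (adjusted p = 0.601 with an estimated correlation, range 0.000852 to 0.601), lost without addback replicate 1 (0.0533). Addback replicate 3 also lay nearer empty vector for this list, with a mean log2(CPM + 1) of 7.34 against 7.12 and 7.17 in the other addback libraries and 7.49 to 7.52 with empty vector.

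Serine and one-carbon metabolism had 14 of 23 genes lower and 3 higher with addback (14 and 4 when adjusted over the list alone). Psat1 fell from 624 ± 19.9 to 228 ± 18.7 CPM, Phgdh, the first enzyme of serine synthesis, from 24.3 to 6.01 CPM and Shmt1 from 117 to 45 CPM (adjusted p = 4.28e-07, 5.71e-06 and 3.25e-07). The list's median was -0.46 and camera's adjusted p = 0.0149 (adjusted p = 0.47 with an estimated correlation, range 0.00171 to 0.47). Of 35 genes of DNA replication and mitosis 20 fell and 5 rose (21 and 5 when adjusted over the list alone), with a median of -0.33 and an adjusted p = 0.00338 (adjusted p = 0.369 with an estimated correlation, range 0.000357 to 0.369). The kinesin Kif11 fell from 673 to 359 CPM and the mitotic activator Cdc20 from 337 to 195 CPM. Nucleotide synthesis, with 9 of 23 genes lower and 1 higher (the same when adjusted over the list alone), missed camera's threshold (adjusted p = 0.0535, range 7.37e-05 to 0.369). It passed without empty vector replicate 3 (0.0483) or addback replicate 3 (0.037). Among its members Rrm2 fell from 1120 to 481 CPM and Atic from 179 to 77.2 CPM.

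Of 23 neuroendocrine and C cell genes 18 rose and 1 fell, as when adjusted over the list alone, with a median of 1.38 and an adjusted p = 1.03e-08 (adjusted p = 0.276 with an estimated correlation, range 3.18e-09 to 0.276). Pcsk2, a second prohormone convertase, rose from 145 ± 7.06 to 961 ± 14.8 CPM and Celf3, a neural splicing factor, from 3.64 to 65.6 CPM (limma adjusted p = 3.81e-09 and 8.65e-09). Of 11 epithelial genes 9 rose and 1 fell, as when adjusted over the list alone, with a median of 2.2 and an adjusted p = 6.8e-05 (adjusted p = 0.229 with an estimated correlation, range 2.72e-05 to 0.229). The keratins Krt7 and Krt18 rose from 11.3 ± 2.53 to 319 ± 32 CPM and from 6.83 to 109 ± 27 CPM (log2 changes 4.71 and 3.79), and Esrp1 from 21.3 to 48.9 CPM. Of 9 fibroblast and mesenchymal genes 4 fell and 2 rose, as when adjusted over the list alone. The list missed camera's threshold (adjusted p = 0.154, range 6.61e-05 to 0.47), and fibronectin (Fn1) stood at 38.3 and 0.298 CPM.

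**Figure D2:**
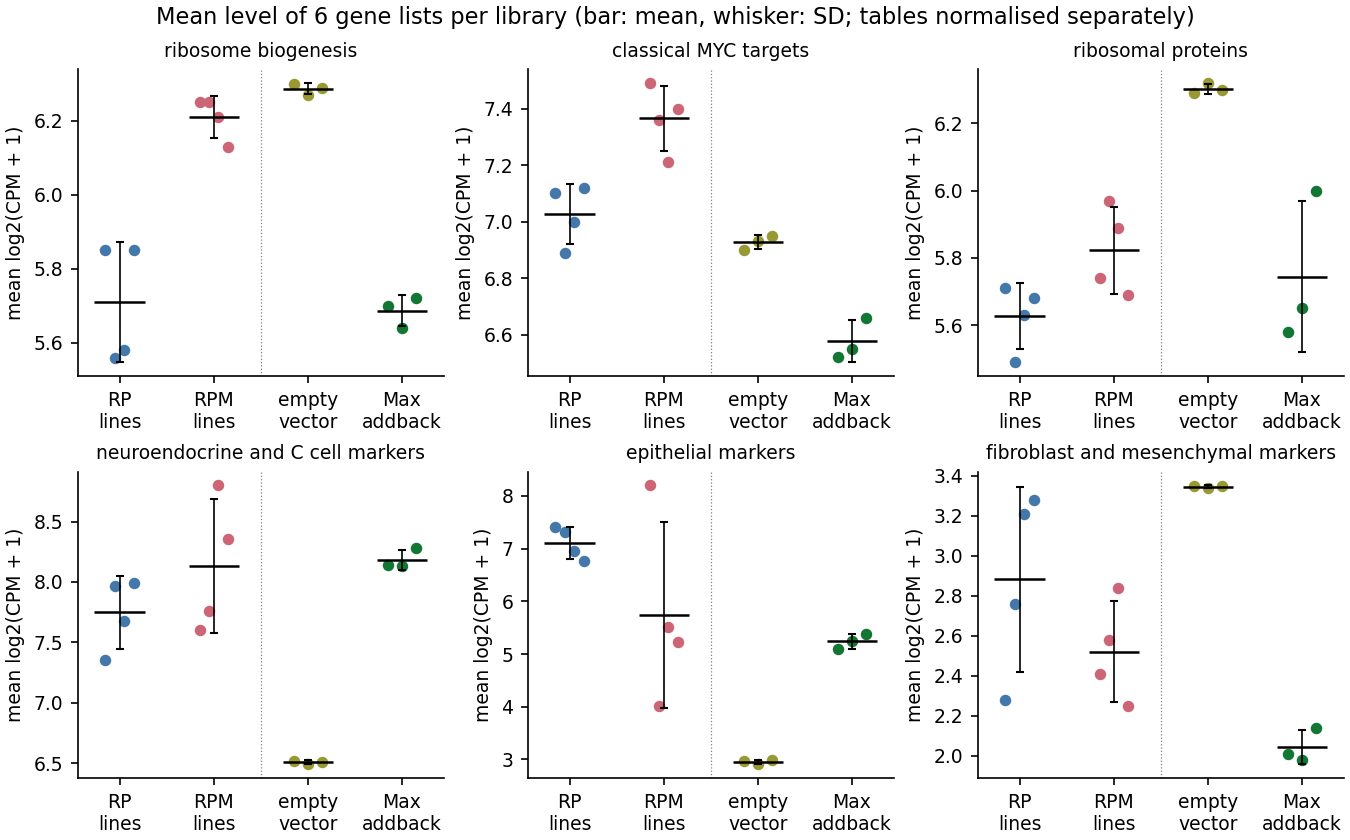
Mean log2(CPM + 1) of the members of 6 gene lists in each library, for RP lines, RPM lines, empty vector and Max addback; each dot is 1 library. The lines and the addback experiment were normalised separately, so levels are compared within each. The ribosome biogenesis mean was 5.71 ± 0.16 in RP and 6.21 ± 0.06 in RPM lines.

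Besides Pcsk1, genes outside these lists also had large changes with addback. Atp2a3, a calcium pump of the endoplasmic reticulum, rose from 9.79 ± 0.827 to 769 ± 22.4 CPM (SD, n = 3 each; log2 change 6.16, SE 0.08, limma adjusted p = 1.17e-10), and the imprinted gene Nnat from 7.5 ± 0.965 to 552 ± 69.2 CPM (log2 change 6.02, SE 0.11, adjusted p = 6.57e-10). Genes with only a few reads with empty vector included Ccn3 (0.194 to 172 ± 9.3 CPM), the potassium channel Kcnj3 (0.381 to 97.2 ± 8.46 CPM), Zdbf2 (0.241 to 91.3 ± 28.7 CPM) and Samd5 (0.241 to 82.3 ± 11.9 CPM). Gabra3, a GABA receptor subunit, the kinase Dapk1 and the phosphatase Dusp22 reached 96.2 ± 10.9, 84.1 ± 12.6 and 61.2 ± 4.55 CPM from 0.095, 0.143 and 0.0509 CPM. Downward, the secreted regulator Igfbp2 fell from 393 ± 16.1 to 5.65 ± 1.2 CPM (log2 change -5.9, SE 0.12, adjusted p = 1.03e-09), Cd109, a cell surface glycoprotein, from 178 ± 9.27 to 1.64 ± 0.573 CPM, the growth factor Igf1 from 91.9 ± 7.08 to 0.801 CPM and the piRNA factor Piwil4 from 97 ± 3.56 to 0.8 CPM (log2 changes -6.1, -5.69 and -5.78). Dcpp1 and Dcpp2 went from 145 and 122 CPM to 0.841 and 0.8 CPM, but are near-identical copies whose reads cannot be told apart with certainty.

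Transcripts of 4 listed Y-linked genes were missing, or nearly so, with addback. Ddx3y (Y, 1260771 to 1286629) stood at 166 ± 9.84 CPM and Eif2s3y (Y, 1010543 to 1028847) at 120 ± 1.43 CPM with empty vector, and no read of either was found in the 3 addback libraries; against a floor of 3 reads in 1 library they were at least 431-fold and 310-fold lower. Kdm5d went from 65.9 CPM to 1 read and Uty from 64.4 CPM to 2 reads over the 3 addback libraries. The untransduced RPM replicate 2 held 125 CPM of Ddx3y, in a table normalised separately.

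In the MYC/MAX/MLX network 12 members were listed; 2 rose and 5 fell, as when adjusted over the list alone. Besides Max, Mlxipl, the glucose-responsive partner of MLX, rose from 22 ± 2.06 to 51.4 ± 1.31 CPM (log2 change 1.19, SE 0.1, limma adjusted p = 4.79e-06). Mnt fell from 89 ± 9.53 to 57 ± 0.637 CPM (log2 change -0.63, SE 0.09, adjusted p = 0.000271), Mxi1 from 180 to 123 CPM (adjusted p = 0.00196) and Mga from 347 to 214 ± 62 CPM (adjusted p = 0.00714). Mlx fell from 63.7 to 50.2 CPM and Mlxip from 84 to 65 CPM (adjusted p = 0.0371 and 0.019). The call of Mlx was lost without empty vector replicate 1 (0.109) or 2 (0.135) or addback replicate 1 (0.116) or 2 (0.126), and that of Mlxip without empty vector replicate 1 (0.063), 2 (0.0626) or 3 (0.0584); their adjusted p reached 0.208 and 0.103 at the highest over all alternatives. As a list the network missed camera's threshold (downward, adjusted p = 0.69, with a median of -0.17 and a mean of -0.01), whereas fry gave upward with an adjusted p = 0.00363. Its alternatives ranged from that value to 0.852. The list includes Max itself, which the vector supplied, so the upward call cannot be read as a result about the other members.

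**Figure D3:**
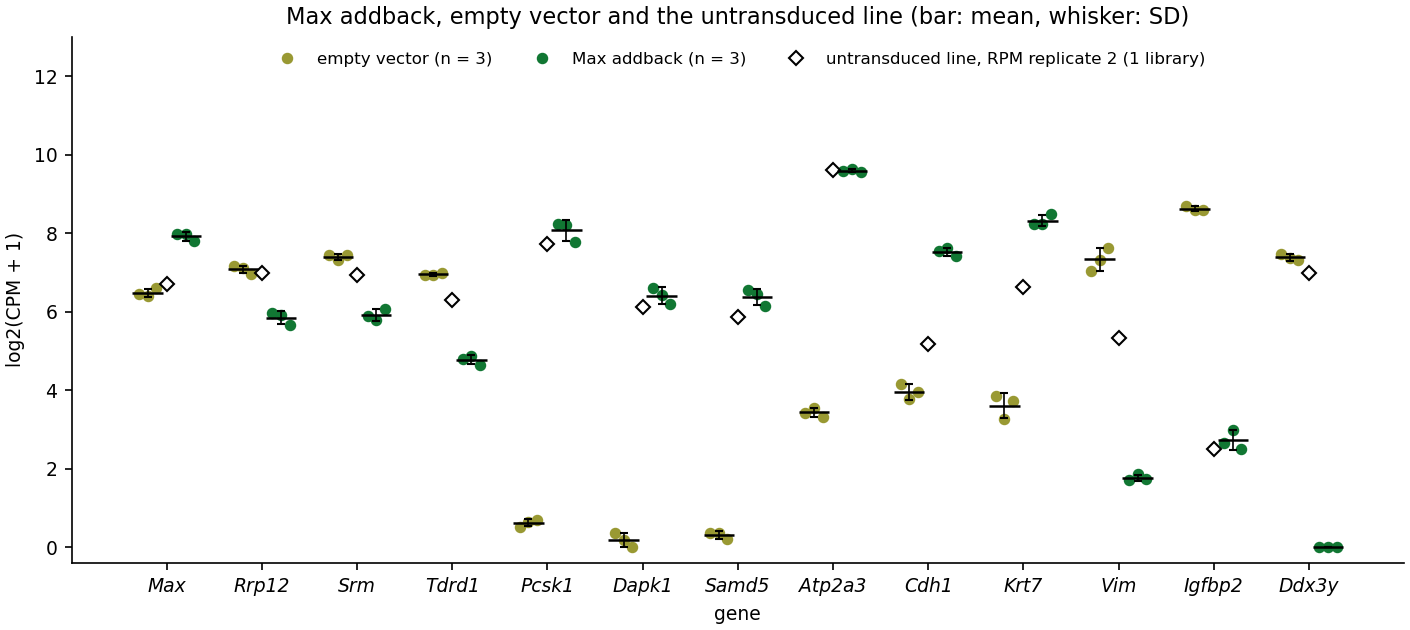
Levels of 13 genes, as log2(CPM + 1), in the 3 empty vector and 3 Max addback libraries (dots; bar, mean; whisker, SD), with the untransduced line, RPM replicate 2, as a diamond. The tables of the line and of the transduced cells were normalised separately. Pcsk1 went from 0.536 to 270 CPM with addback and stood at 210 CPM in the untransduced line.

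For many of the genes that differed most, the untransduced line RPM replicate 2 stood nearer the addback than the empty vector libraries, as far as levels from separately normalised tables can be set side by side. It held Pcsk1 at 210 CPM, Atp2a3 at 779 CPM, Dapk1 at 68.2 CPM, Samd5 at 57.5 CPM, Dusp22 at 24.9 CPM and Igfbp2 at 4.61 CPM. Vim stood at 38.9 CPM in that line, Cdh1 at 35.3 CPM and Krt7 at 97.5 CPM, between the other values. The lists called with addback went either way. For ribosome biogenesis the line's mean log2(CPM + 1) was 6.25, against 6.29 with empty vector and 5.69 with addback. It also lay nearer empty vector for MYC targets (7.36, against 7.2 and 6.89), replication and mitosis (7.61, against 7.71 and 7.45) and epithelial genes (4.01, against 2.96 and 5.24). It lay nearer addback for ribosomal proteins (5.97, against 6.3 and 5.74), translation initiation (7.3, against 7.51 and 7.21) and neuroendocrine genes (7.76, against 6.51 and 8.18), and about midway for serine and one-carbon metabolism (5.47, against 5.7 and 5.25).

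Over all 14056 genes, limma called 3896 higher and 3582 lower with addback, 53.2% of the genes; 1480 and 708 changed at least 2-fold. An unadjusted p under 0.05 was found for 8280 genes. Libraries did not overlap at 7361 of the 7478 called genes and at 61.9% of all genes, against 10% by chance. Addback replicate 3 stood apart from the other addback libraries: chi-square per degree of freedom between pairs was 16.3 and 13.8 with it and 1.88 without it, and leaving it out gave 4575 higher and 4460 lower. On the recovered reads edgeR's quasi-likelihood test called 3893 higher and 3537 lower and DESeq2 3537 and 3168. Of 24 lists, 8 passed by camera, 0 with an estimated correlation (smallest adjusted p 0.229) and 17 by fry. In 1 fit over all 14 libraries 1475 were higher and 1025 lower, and without scaling beyond library size 60.7% of calls were higher, against 52.1%.

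The relation of the comparisons was then tested, since a gene that follows MAX would move one way where Max is lost and the other way where it is returned. Of 46 genes called in RPM lines and listed in both tables, 38 were also called with addback. Opposite directions were found for 30 of these and the same direction for 8, where 12.0 and 12.4 would come by chance, and Fisher's exact test across genes, which are not independent, gave a two-sided p = 0.0026. Tdrd1 rose in RPM lines and fell with addback from 123 ± 3.23 to 26.3 ± 2.14 CPM (SD, n = 3 each; log2 change -2.18, SE 0.09, limma adjusted p = 3.41e-08). Taf4b fell from 37.1 to 14.6 CPM and Ltv1 from 101 to 47.4 CPM with addback, as did Rrp12, Rcl1 and Mnt. Rtn1, lower in RPM lines, rose with addback from 5.63 to 30.9 CPM (log2 change 2.27, SE 0.12, adjusted p = 2.81e-07), Cdkn1c from 9.52 to 17.4 CPM and Nrxn3 from 0.723 to 4.3 CPM. Arnt2, Plxnd1 and Fzd3 were lower in both comparisons.

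**Figure D4:**
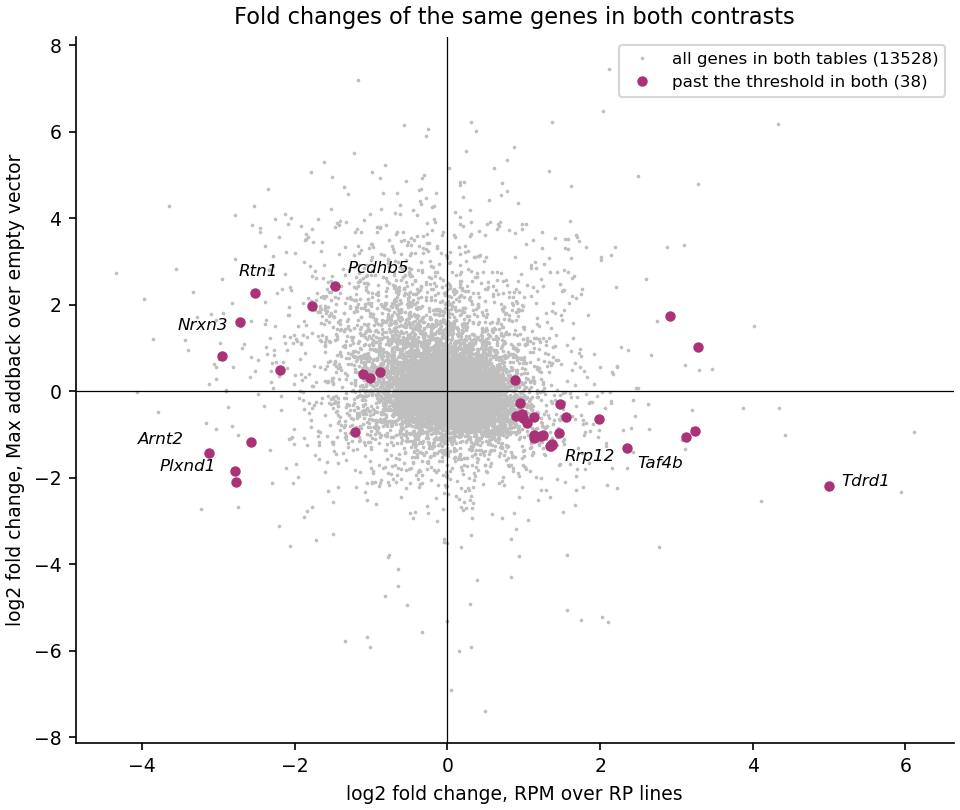
Log2 fold change with Max addback over empty vector (vertical axis) against that in RPM over RP lines (horizontal axis) for the 13528 genes in both tables, 1 grey point each; the 38 genes past the threshold in both are drawn large. Of those, 30 lie at the upper left and lower right, where the directions are opposite, and 8 in the others.

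The 30 genes depended on the line that both experiments share and on single lines. Without RPM replicate 2 there were 6 opposite and 4 same, and Fisher's exact two-sided p was 1. The count of opposite genes was 4, 6, 0 and 11 without RP replicates 1 to 4, and 134 (RPM replicate 1), 0 (RPM replicate 3) and 0 (RPM replicate 4) without another RPM line. Across all 13528 genes the log2 changes correlated weakly, with Spearman's rho -0.174 and Pearson's r -0.165 across genes that are not independent replicates; rho was -0.082 without RPM replicate 2, and 13 of the 35 splits of the 8 lines into groups of 4, the real one included, gave an absolute rho as large. Empty vector over addback sets cells without added Max against cells in which Max averaged 240 CPM. RP lines averaged 54.6 CPM of Max, in a table normalised separately. The log2 change of RPM over RP and that of empty vector over addback were compared gene by gene with limma on the recovered reads. The difference is the first minus the second. The 2 changes differed at 1955 genes, 1220 with a positive and 735 with a negative difference. The counts were 1386 and 877 without RPM replicate 1, but 895 and 470 without RPM replicate 3, 878 and 461 without RPM replicate 4 and 895 and 478 without RP replicate 3. Without quality weights for the libraries they were 576 and 378. For Rrp12, Rtn1 and Ltv1 no difference was called (0.14, -0.13 and 0.04 on the log2 scale; limma adjusted p = 0.683, 0.826 and 0.917). For Tdrd1 the difference was 5.48 (adjusted p = 0.00363), for Pcsk1 10.91 (adjusted p = 0.000298), and for Cdkn1c -2.26 (adjusted p = 0.0024). These differences are on voom's log2 scale of reads, not on the log2(CPM + 1) scale of the changes given for each comparison. For genes with almost no reads in a group, such as Tdrd1 in RP lines, they can be much larger than those changes would give.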

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

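All tests of the Y-linked transcripts, of Xist and of the untransduced line in this part were chosen after the values they explain had been seen. The counts over other splits of the libraries were planned. The test of the difference between the comparisons was planned for raw counts only. Its use on recovered reads was chosen after the deposited values were seen to be normalised. Genes were looked at again for either of these reasons: 1 library of a group of 4 stood far from the rest by Dixon's test, or the change in RPM over RP lines differed from the change in empty vector over addback by a test of the difference.

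Of 160 groups of 4 lines tested over the named genes, 15 held a library far from the others. Chance gives about 1 in 20 only for normally distributed values and independent genes. The test used untransformed CPM, where a high library stands out more easily, and each of the 15 was the highest of its group. An excess over chance is therefore not shown. RP replicate 4 stood out most often. It held Tdrd1 at 4.71 CPM (others up to 0.122), Stag3 at 46.6 CPM (others up to 3.01), Pcsk2 at 739 CPM (others up to 404), Phgdh at 8.24 CPM (others up to 3.61) and Trp53 at 16.6 CPM (others up to 10.2). RPM replicate 1 held Mycl at 320 CPM (others up to 6.61) and Rbm46 at 48.4 CPM (others up to 20.9). RPM replicate 2 held Psat1 at 217 CPM (others up to 114) and Piwil4 at 4.49 CPM (others up to 0.592). Myc was at 2.25 CPM in RPM replicate 3 (others up to 0.255) and Samd5 at 108 CPM in RPM replicate 4 (others up to 58.1). RP replicate 1 held Cdh1 at 1120 CPM (others up to 701) and Shmt1 at 83.3 CPM (others up to 54). Mlx was at 61.2 CPM in RP replicate 2 (others up to 46.5) and Igfbp2 at 80.6 CPM in RP replicate 3 (others up to 4.24).

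Of 78 named genes in both tables, 47 differed between the comparisons by the limma test of the difference, against 1955 of all 13528 genes. Many named genes were chosen for large changes in these same comparisons, so the 47 do not measure how often genes differ. The values are the log2 change RPM over RP minus the log2 change empty vector over addback, on voom's scale of reads and not on that of log2(CPM + 1). Of the named genes known from the germline, Tdrd1 differed by 5.48, Rbm46 by 5.68, Stag3 by 6.43 and Ccdc36 by 3.03, but the piRNA factor Piwil4 by -9.62. Upward differences were also found for Max at 2.11, Zscan18 at 1.78, Nol8 at 0.96, Scfd2 at 1.2 and Pcdhb5 at 1.27. The neuroendocrine genes Pcsk1, Pcsk2 and Celf3 differed by 10.91, 3.42 and 3.32, Krt7 by 3.46, Casr by 3.34 and Tert by 3.81. The genes with the largest rises with addback followed: Zdbf2 13.88, Gabra3 11.48, Kcnj3 10.08, Dapk1 9.16, Dusp22 8.87, Ccn3 8.54, Samd5 7.78, Nnat 6.57 and Atp2a3 5.7. Downward, Arnt2 differed by -4.95, Plxnd1 by -5.46, Fzd3 by -2.18, Cdkn1c by -2.26, Fam102b by -1.73 and Mycl by -4.4. Genes that fell far with addback differed by -7.28 (Igfbp2), -7.36 (Igf1), -6.42 (Vim) and -6.69 (Fn1), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty by -10.96, -11.28, -9.44 and -8.99. Downward differences were also found for Srm at -0.84, Nop58 at -0.53, Rps19 at -0.98, Rpl22 at -1.12, Eif3a at -0.56, Atic at -0.84, Psat1 at -0.91 and Phgdh at -2.13. For the ribosome factors Rrp12 and Ltv1 no difference was called, and the nucleolar gene Nol8 differed upward, as given above.

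Chance as a source was examined by regrouping libraries. The count of genes called between RPM and RP lines fell to 0 by limma without RP replicate 3, RPM replicate 3 or RPM replicate 4. Of 35 splits of the 8 lines, only 1, the real one, gave as many called genes (48, highest other 36). As the smallest share that 35 splits allow, this leaves chance unlikely as the source of that count but not excluded. Likewise 1 of 35, the real one, gave as many called lists by camera with its preset correlation (12, highest other 11), but by a margin of 1 list: 3 other splits gave 11 and 2 gave 10, and 0 lists passed with an estimated correlation. For genes opposite in both comparisons the real split also stood alone (1 of 35; 30, highest other 11). This says nothing about the directions, since 28 of the 34 other splits called no gene by limma and so had 0 opposite ones, and without RPM replicate 2 there were 6 opposite and 4 same (Fisher's exact two-sided p = 1). Chance could not be excluded for the correlation across genes, which 13 of 35 splits matched (0.174 in size, highest other 0.281). For the addback experiment 10 splits are too few: 1 gave as many genes (7478, highest other 0 by limma, where the real split has 8280 at an unadjusted p under 0.05), and 2 gave as many lists (8, highest other 12). For the difference between the comparisons, 1 of 60 regroupings gave as many genes (1955, highest other 1889). The 5 other regroupings that kept the addback libraries as labelled gave 1308 to 1889, and the 54 that regrouped those libraries gave 0 to 1, so the size of that count follows the addback experiment.

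The first pattern weighed is the missing Y-linked transcripts in the 3 addback libraries. An origin in another of the sequenced lines is argued against: the deviations of the addback libraries correlated at 0.75 with RPM replicate 2 and at most at 0.08 with another line. Silencing by MAX at the level of RP lines is argued against by 3 RP lines, labelled without a Max mutation, that hold Ddx3y at 10 CPM or more. Max averaged 54.6 CPM in RP lines and 240 CPM with addback, in separately normalised tables. Silencing at the higher level was therefore not tested. Loss of the Y chromosome was judged first by all 6 listed Y genes, and up to 196 reads of Gm47283 (Y, 90784738 to 90816464, named after its values were seen) in 1 addback library went against it; that test was then set aside and its bound rewritten, because RP replicate 2 and RPM replicate 3, without any Ddx3y read, hold Gm47283 at 14.8 and 12.1 CPM, although RPM replicates 1 and 4, with Ddx3y, have 0.893 and 3.59 CPM. Over the 5 listed genes that those lines lack, at most 2 reads were found in an addback library, so cells without the Y chromosome may be the source, but as these genes lie between 897788 and 1286629 a loss or silencing of that segment stays open.

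The second pattern is Xist together with Y-linked transcripts in RP replicate 4, at 344 CPM of Xist against at most 0.963 CPM in RP replicates 1 and 3, 1960 CPM in RPM replicate 3 and 5040 CPM in RP replicate 2. Reads assigned to the wrong library at a rate of 1% or less are argued against, since Xist stood at 0.0683 of the highest line's level and over 15 genes that the other RP lines nearly lack RP replicate 4 held no less than 0.0727 of the level of RPM replicate 3. RNA or cells of RPM replicate 3 may be in the library, though the test does not point to that line: Xist stood at 0.176 of that line's level, within the range of the same share over the 15 genes (0.0727 to 0.357, median 0.156). The other RPM lines held Xist at 0.383 to 0.748 CPM and so cannot have supplied it, yet gave like shares for RPM replicate 1 (median 0.108, 0.053 to 0.267, 8 genes) and RPM replicate 4 (0.103, 0 to 0.194, 11 genes) and a lower one for RPM replicate 2 (0.0282); RP replicate 2 could also be the source, as Xist stood at 0.0683 of its level, against a median of 0.0866 (0.00388 to 0.578) over 20 genes that RP replicates 1 and 3 nearly lack. Whether any other line was a source is not settled, as several criteria for choosing genes were tried, Xist had been seen beforehand and libraries almost without Xist gave medians of 0.0376 and 0.0157 for RP replicate 2; a mixed sample of cells within the line stays open and was not tested.

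The third pattern is that genes at least 4-fold higher with addback stood near the level of the untransduced line, RPM replicate 2, labelled as Max mutant; it took the place of tests of RPM replicate 1, given with the other observations. If that line lacks MAX as labelled, which its whole-gene Max level of 103 CPM does not check, expression that MAX returned is argued against for these genes as a set, since at 76.5% of 562 the line lay nearer the addback than the empty vector mean (66.7% of all genes called higher, and 70.6% and 89.4% of those with log2 changes of at least 1 and 4). An offset between the separately normalised tables is argued against, as the line lay a median log2 difference of 2.1 above empty vector over these genes and 0.01 over all genes. A change of the empty vector cultures away from the line may account for the pattern: at 80.2% of the 562 genes the empty vector mean lay below all 8 lines, while the addback mean lay above all 8 at 8.54% (20.8% and 9.65% over all genes), although genes chosen for a large rise favour low empty vector and high addback levels; of 129 genes at least 4-fold lower, 74.4% had the empty vector mean above all lines and 66.7% the line nearer addback, but among the 20 with log2 falls of at least 4 the line lay nearer addback at 10 and nearer empty vector at 10. Whether the lack of MAX, transduction or time in culture changed those cultures stays open.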

How the results depend on the processing

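The count tests on recovered reads, the pseudocounts, the chromosome medians and the exact test of list means were chosen after seeing the data. So was leaving out libraries in the test of the difference, other than RPM replicate 2. The test of the difference was itself planned for raw counts only and was run on recovered reads. The other tests were planned. A run without any filter could not be made, since the authors' own filter cannot be undone.

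The calls between RPM and RP lines depended on the processing. Against 30 higher and 18 lower by limma-trend, DESeq2 gave 350 and 308, edgeR's exact test with trended dispersion 235 and 327 (32 of the 48 shared), 1 fit over all 14 libraries 464 and 394, limma voom 1 and 0 (2262 at an unadjusted p under 0.05), edgeR's quasi-likelihood test 1 and 2 (2133), and an adjusted p under 0.01 in limma-trend 0 and 0. Leaving out 1 library gave 0 to 77 higher and 0 to 184 lower, with none without RP replicate 3, RPM replicate 3 or RPM replicate 4 and the most without RPM replicate 1, where all 48 genes remained. In the exact test, 48.5% of calls in simulated lines with 4-fold changes were unchanged genes. In the 1 fit over all 14 libraries the smaller spread between libraries of the addback experiment enters the error of the lines. Its 464 and 394 calls thus do not measure the spread between lines alone. For the other differences the cause was not tested. The counts stayed within 1.5 times under size factors, no scaling, a stricter filter, pseudocounts, chromosome medians and a 2-fold minimum. The genes called were not all the same: with chromosome medians subtracted 37 were called, 30 of them among the 48. With the replicate number as a block limma called 0 higher and 0 lower (2463 unadjusted), edgeR's quasi-likelihood test 0 and 0 (2201), and no gene was opposite in both comparisons (0). The numbers are not known to pair the libraries: same-numbered lines correlated at 0.42, 0.05, 0.01 and 0.13 and addback libraries at 0.06, 0.04 and 0.1, and not every library correlated best with its own number. The block also removes degrees of freedom. It moved no count of the addback experiment by over 1.5 times, and the 1 list call it changed was glycolysis with addback, at 0.0485 (0.00235 to 0.87 over all alternatives). The addback counts of 3896 and 3582 moved by more only with a 2-fold minimum, to 1480 and 708, and in 1 fit over all 14 libraries, to 1475 and 1025, where the larger spread of the lines enters the error. The 30 opposite genes became 6 without RPM replicate 2, 0 to 134 over all libraries left out, 286 by DESeq2, 229 by edgeR's exact test and 3 by its quasi-likelihood test, and rho went from -0.174 to -0.082 without RPM replicate 2, with a range of -0.239 to -0.082 over libraries left out. In the test of the difference between the 2 contrasts, 1955 genes became 954 without quality weights, 762 at an adjusted p under 0.01 and 1339 to 2379 over libraries left out. Lists called fell from 12 to 0 in the lines and from 8 to 0 with addback under an estimated correlation in camera, and fry called 4 and 17. The network, a list that includes the added Max, turned from downward to upward with addback by fry (0.00363). For single lists, 264 alternative values in the lines kept their direction and call 224 times, were weaker 33 and stronger 7 times; of 216 with addback 192 kept both, 9 were weaker, 14 stronger and 1 reversed. For named genes in the lines, 1391 of 1666 alternative values kept both, 238 were weaker, 37 stronger and 0 reversed by any tool run, and 0 of the 23 called genes kept the call under every alternative. With addback 1505 of 1536 kept both, 26 were weaker, 5 stronger and 0 reversed, and 63 of 72 called genes kept the call throughout. Depth limits genes near 3 reads in a library, 0.353 to 0.458 CPM. For other genes, depth and the spread between libraries were not varied against each other. With 200 genes changed 2-fold, limma-trend recovered 0% in simulated lines and 98% in the simulated addback experiment. The 0% belongs to that setting: in the real lines 24 of 30 higher and 16 of 18 lower genes changed at least 2-fold, so smaller changes were also called.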

Other observations

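The tests of RPM replicate 1 and of chromosome medians in this part were chosen after results had been seen; the gene lists were planned.

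Several gene groups not yet described did not pass by camera in RPM against RP lines. Translation initiation (21 genes, median log2 change 0.15, adjusted p = 0.248), MLX partner targets with lipogenesis (15 genes, 0.09, 0.248), p53 targets (14 genes, 0.16, 0.232), interferon response (13 genes, median -0.1 and mean -0.02 with camera upward, 0.838), and markers of neuroendocrine and C cells (23 genes, 0.17, 0.304), thyroid follicular cells (3 genes, 0.62, 0.304), fibroblasts (8 genes, -0.57, 0.304) and Schwann cells (4 genes, 0.36, 0.304) missed the threshold, with 0 members past it by limma over all genes and, adjusted over the list alone, 1 higher among p53 targets and 1 among follicular genes. Glycolysis (20 genes, median 0.21, adjusted p = 0.194), the ATF4 response (16 genes, -0.34, 0.201) and cholesterol synthesis (22 genes, -0.09, 0.201) also had 0 members past limma's threshold, over all genes and adjusted over the list alone, but each passed on leaving out 1 line: glycolysis without RP replicate 3 (0.00878), the ATF4 response without RPM replicate 3 (0.00544) and cholesterol synthesis without RPM replicate 1 (0.00466). Their alternatives reached 0.936, 0.728 and 0.813. The 2 listed leukocyte genes (median 0.09), the parathyroid gene Casr (log2 change 0.04, limma adjusted p = 0.976) and the 5 sex-linked genes (median 0.15, mean -0.26) were not tested as lists.

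With addback, glycolysis had 12 of 20 genes lower and 3 higher (13 and 3 adjusted over the list alone), a median log2 change of -0.57 and a camera adjusted p = 0.0679, passing without empty vector replicate 2 (0.0384) or addback replicate 3 (0.00235), with up to 0.87 over its alternatives. Oxidative phosphorylation had 8 of 35 lower and 1 higher, the same adjusted over the list alone, a median of -0.14 and an adjusted p = 0.0679, or 0.000176 without addback replicate 3 and up to 0.87. Lysosomal genes had 10 of 27 higher and 2 lower (9 and 2 adjusted over the list alone; 0.263), cholesterol synthesis 7 of 22 higher and 4 lower (0.791), interferon response 5 of 11 higher and 2 lower (0.512), MHC class I presentation 3 of 10 higher and 3 lower (0.905) and the ATF4 response 5 of 16 higher and 3 lower (0.898), each with the same counts adjusted over the list alone unless given. p53 targets had 7 of 14 lower and 2 higher (8 and 2 adjusted over the list alone; 0.217). MLX partner targets had 6 of 15 higher and 6 lower, with a median of -0.03, a mean of 0.21 and camera upward (0.884). Germline genes had 4 of 15 higher and 2 lower (median 0.21, 0.488); the 2 were Tdrd1 and Stag3, so the list as a whole did not follow them. Of marker lists, Schwann cell genes had 3 of 4 higher and 1 lower (0.217), follicular genes 1 of 5 each way (0.907) and endothelial genes 1 of 4 each way (0.905), with the same counts adjusted over the list alone. Casr, the calcium-sensing receptor listed for parathyroid, rose from 11.9 to 129 ± 56.6 CPM (SD, n = 3; log2 change 3.22, limma adjusted p = 1.07e-05), 1 of 2 listed leukocyte genes rose, and 4 of 5 sex-linked genes, the Y-linked ones, fell.

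RPM replicate 1 differed from the other RPM lines. Without it limma called 261 genes; at 88 of these RPM replicate 1 lay nearer the mean of the other RPM lines and at 173 nearer the RP mean, 33.7% nearer its own group, though genes called without a library are not chosen evenly with respect to it. Its ribosome biogenesis mean, as log2(CPM + 1), was 6.25 and the highest RP line's 5.85; its epithelial mean was 8.2 and the highest of the other RPM lines 5.51. No explanation of this was tested.

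Median log2 changes also differed between chromosomes. In the lines 10 of 20 chromosomes lay farther from the median of all genes (0.01) than the highest of 1000 permutations of genes, 0.1, with chromosome 13 at 0.37, chromosome 8 at 0.23 and chromosome 7 at -0.27. With addback 9 lay beyond 0.12, with chromosome 15 at 0.23 and chromosome 4 at -0.27. The permutations were of genes and not of libraries, so they do not measure the spread between lines or between addback libraries. Whether a shift rests on single libraries was not tested.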
